A study of Mus musculus with 3 samples.

How the data were processed

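Serum was separated from blood of 8-week-old male mice by centrifugation for 3 min, per the labels' protocols, and RNA from 200 µL of serum was extracted with each of 3 kits. Cy3-labelled RNA from 1.8 ng per extract was hybridised to 1-colour Agilent mouse miRNA arrays, and the 3 arrays lay on the same slide and were scanned in the same scan at the same detector setting, per the file headers. Slide and scan therefore do not separate the kits. The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1, per the file headers, and version 11.5 is named in the submitters' processing notes. Background was subtracted with spatial detrending, so that some deposited intensities are negative, and no normalisation between arrays was recorded, per the file headers. The deposited value table held the same intensities, with each of 58594 values per array within 0.50% of the scanner value matched by spot number; its column medians were −2.77 for exoRNeasy, −1.51 for miRNeasy advanced and −1.44 for mirVana PARIS, over probes that are mostly at background. Its scale is thus linear and not centred, and the deposited values are single-array levels with no direction to settle.

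Of 58594 spots per array, 56430 were not controls and carried 4415 probes for 1881 mouse miRNAs, with 1 to 4 probes per miRNA and 7 to 30 spots per probe. Spots flagged as outliers were left out, 1515 on the exoRNeasy array, 1474 on the miRNeasy advanced array and 1427 on the mirVana PARIS array. No spot was saturated. A probe counted as detected when over 0.5 of its remaining spots were flagged well above background, which held for 128, 115 and 213 probes in the same order, and a miRNA when at least 1 probe was. Signal limited what could be compared. The lowest signal among detected probes was 21.6 on the exoRNeasy array, 12.2 on the miRNeasy advanced array and 8.81 on the mirVana PARIS array, against mean negative-control signals of 5.41, 4.92 and 5.49. The number of arrays, 1 per kit, limited the precision.

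Spot signals were raised to at least 1, converted to log2 and averaged per probe, and the 75th percentile over the 106 probes detected on all 3 arrays was subtracted, at 7.05 for exoRNeasy, 6.21 for miRNeasy advanced and 8.02 for mirVana PARIS. A miRNA took the value of its probe detected on most arrays, then of highest mean. Where miRNAs had several probes the probe ratios had opposite signs for 5 of 39 miRNAs in exoRNeasy against miRNeasy advanced, 3 of 43 in exoRNeasy against mirVana PARIS and 5 of 42 in miRNeasy advanced against mirVana PARIS. The error of a log2 ratio combined the standard errors between spots on both arrays. The median standard deviation between spots of a detected probe was 0.12, 0.15 and 0.14 for exoRNeasy, miRNeasy advanced and mirVana PARIS. No test of significance was possible with 1 array per kit. miRNAs detected on 1 of 2 arrays were given a bound, the scaled level on the bright array against the higher of the lowest detected level and the measured level on the dim array. All differences, bounds included, are after scaling unless said to be unscaled.

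Before the data were examined, 16 lists were fixed: red blood cell, platelet and white blood cell, let-7, liver, heart and skeletal muscle, brain with pancreas and kidney, miR-200 and miR-203, miR-29 and miR-30, low-GC miRNAs, the Dlk1-Dio3 cluster, G-rich or C-rich miRNAs, the Sfmbt2 cluster, names numbered 1000 or higher, lower numbers with let-7, 5p arms and 3p arms. The last 4 and the Sfmbt2 list follow from names. A list with at least 3 members detected on both arrays was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, each member drawn from a window of 11 miRNAs of neighbouring mean level. The percentile describes these arrays and is not a p-value. The miRNAs named in the text follow a rule fixed at the same time: per comparison up to 10 highest and 10 lowest log2 ratios of at least 2-fold and over 3 spot errors, up to 5 bounds per direction, up to 4 members of each list with the largest absolute ratio among those detected on all 3 arrays, and 8 miRNAs fixed by name, miR-451a, miR-16-5p, miR-122-5p, miR-223-3p, miR-1a-3p, miR-21a-5p, let-7a-5p and miR-486a-5p. The miRNAs named as detected in some lists, those named as brighter without scaling, and miR-26a-5p, were named after their values were seen.

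The calling step was tested on simulated data for exoRNeasy against mirVana PARIS. All 15 detected miRNAs changed by 1.5 log2 units were found past 2-fold and 0 of 49 unchanged ones were called. The simulated arrays shared 1 level profile and differed by array scale and spot noise. Their ratios were centred on the miRNAs known to be unchanged, which real data do not allow. The simulation thus did not test the scaling, the background or the extraction, and changed miRNAs that went undetected are not among the 15. Alternatives covered the scaling, the background correction, the value per miRNA, detection, filters on dim probes, outlier spots, the value table and the fold threshold. The normexp correction planned on mean spot signals, and the mean signals without correction, were not run because the files used here hold median spot signals; both were run on the medians instead, normexp with an offset of 50, and scaling by the labelling spike-in was added, all chosen after the files were seen. Gene neighbours were looked up in the mouse annotation of assembly GRCm38.p6 by gene symbol, with a single locus for 113 of 137 detected miRNAs; the arrays are annotated on another build, per the file headers, so no coordinates are given. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for normexp.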

Results

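MicroRNAs were measured in serum of 8-week-old male C57BL/6NJcl mice after RNA extraction in 3 ways from 200 µL of serum, with 1 microarray for each. The first RNA came from the miRNeasy serum/plasma advanced kit, a column kit for small RNA in blood fluids. The second was taken from the aqueous layer of serum mixed with 700 µL of QIAzol, a phenol and guanidine reagent, and was bound to the columns of the exoRNeasy midi kit; the labels describe this arm as a measure of total serum RNA. The third came from the mirVana PARIS kit, which uses organic extraction and a glass-fibre filter. For every array 1.8 ng of RNA was labelled with Cy3 and hybridised to a mouse miRNA array with 4415 probes for 1881 miRNAs. The labels do not say whether the extractions shared a serum pool. With 1 array per kit there was no replicate check, so no p-value was computed; errors are standard errors between replicate spots of a probe on these arrays, which cover the array step and neither the extraction nor the mice. Ratios are log2 ratios after scaling each array to its own 75th percentile over the 106 probes detected on all 3 arrays.

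The mirVana PARIS array had the widest set of detected miRNAs, 134 of 1881, against 83 on the exoRNeasy array and 71 on the miRNeasy advanced array. A core of 67 miRNAs was detected on all 3 arrays. It held red blood cell miRNAs such as miR-451a and miR-16-5p, the myeloid and platelet miRNA miR-223-3p, the liver miRNA miR-122-5p, the muscle miRNAs miR-1a-3p, miR-133a-3p and miR-133b-3p, and 7 members of the let-7 family, regulators of developmental timing and cell growth. The red cell miRNA miR-451a, which matures without Dicer, had a scaled log2 level of 5.56 on the exoRNeasy array, 6.06 on the miRNeasy advanced array and 6.12 on the mirVana PARIS array. All 71 miRNAs of the miRNeasy advanced array were also detected on the mirVana PARIS array. A further 50 miRNAs were detected on the mirVana PARIS array alone, 13 on the mirVana PARIS and exoRNeasy arrays, and 4 on the mirVana PARIS and miRNeasy advanced arrays. The exoRNeasy array alone detected miR-429-3p, miR-483-3p and miR-1894-5p, and 1744 miRNAs were well above background on none of the arrays. With every probe of a miRNA required to be above background, the detected numbers were 75, 44 and 41 in the same order. With the scanner software's own detection flag they were 161, 134 and 97.

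Most tissue lists fixed before the data were examined were only partly detected. On the mirVana PARIS, exoRNeasy and miRNeasy advanced arrays, 14, 12 and 12 of the 19 red blood cell miRNAs on the array were detected. The corresponding numbers were 14, 10 and 8 of 21 for platelet and white blood cell miRNAs, 6, 4 and 4 of 11 for liver miRNAs, and 4, 3 and 3 of 9 for heart and skeletal muscle miRNAs. Of 14 miRNAs of brain, pancreas and kidney, the mirVana PARIS array detected 3, miR-375-3p, miR-128-3p and miR-10a-5p, and the exoRNeasy and miRNeasy advanced arrays detected 0. The epithelial miR-200 and miR-203 list of 7 had miR-200a-3p and miR-200b-3p detected on the mirVana PARIS and exoRNeasy arrays, with miR-203-3p and miR-205-5p on the mirVana PARIS array alone and miR-429-3p on the exoRNeasy array alone. None of the 43 miRNAs of the imprinted Dlk1-Dio3 cluster, which is active in embryo, placenta and brain, was detected on any array. Of 61 miRNAs named like members of the Sfmbt2 cluster, miR-466i-5p was the 1 detected.

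Before scaling, the same mass of labelled RNA gave more miRNA signal from mirVana PARIS RNA than from the other extracts. Over the 67 shared miRNAs the median difference per miRNA was 3.12-fold for the mirVana PARIS array over the miRNeasy advanced array. It was 1.62-fold for mirVana PARIS over exoRNeasy and 1.94-fold for exoRNeasy over miRNeasy advanced. Of the 71 miRNAs detected on both the mirVana PARIS and the miRNeasy advanced arrays, 69 were brighter on the mirVana PARIS array. On the miRNeasy advanced array miR-1249-3p and miR-3473f were brighter, by 0.21 ± 0.13 and 0.098 ± 0.09 log2 units, less than 3 spot errors. The muscle miRNAs miR-133b-3p and miR-133a-3p differed most under the main processing, at −3.15 and −3.14 on the log2 scale for miRNeasy advanced minus mirVana PARIS; with normexp, a model-based background correction run on pixel medians, they stood at −1.85 and −1.57 and were not the 2 largest. The probes of the labelling spike-in RNA differed between these 2 arrays by −0.13 ± 0.12 (SD, 4 probes) and those of the hybridisation spike-in by −0.01 ± 0.06 (SD, 4 probes). The median miRNA difference of −1.64 lay outside the range of both. The hybridisation spike-in was brighter on the exoRNeasy array, by 0.42 ± 0.06 than on the miRNeasy advanced array and by 0.41 ± 0.11 than on the mirVana PARIS array (SD, 4 probes), while the labelling spike-in differed by −0.12 ± 0.08 and −0.25 ± 0.18 for exoRNeasy minus the same 2 arrays. The median miRNA differences were 0.96 and −0.69. With the pixel medians in place of the background-corrected signal, the median for miRNeasy advanced minus mirVana PARIS came to −1.05 without background correction and to −0.93 with a model-based one.

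**Figure D1:**
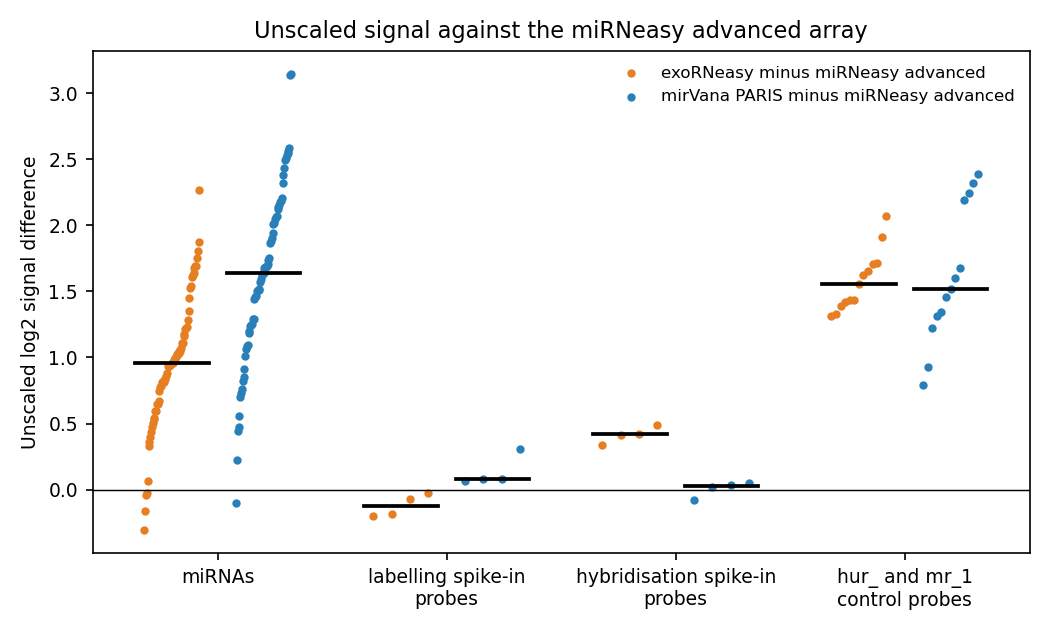
Unscaled log2 signal of the exoRNeasy array (orange) and of the mirVana PARIS array (blue), each minus that of the miRNeasy advanced array, for the 67 miRNAs detected on all 3 arrays, 4 labelling spike-in probes, 4 hybridisation spike-in probes and 13 control probes whose targets the files do not give. Each point is a miRNA or probe and each black bar a median; the miRNA medians lie at 0.96 and 1.64, the labelling spike-in medians at −0.13 and 0.08, and the hybridisation spike-in medians at 0.42 and 0.027.

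The exoRNeasy and mirVana PARIS arrays, the comparison of the total serum RNA arm with organic extraction on a glass-fibre filter, had the most miRNAs past 2-fold under the main scaling; without scaling the miRNeasy advanced and mirVana PARIS arrays had the most. Of 80 miRNAs detected on both, 20 were at least 2-fold higher on the exoRNeasy array and 2 at least 2-fold lower, and all 22 differences exceeded 3 times the spot error. The 20 included 5 of the 7 let-7 list members detected on both arrays, with let-7c-5p at 3.91-fold (log2 1.97 ± 0.06), let-7b-5p at 3.37-fold, let-7a-5p at 3.22-fold and let-7f-5p at 2.81-fold. The epithelial miRNAs miR-200a-3p and miR-200b-3p, repressors of the transcription factors Zeb1 and Zeb2, were 6.00-fold and 4.72-fold higher (log2 2.58 ± 0.08 and 2.24 ± 0.05). The lower miRNAs were miR-144-3p, which is made from the same red cell transcript as miR-451a and was 3.04-fold lower (log2 −1.60 ± 0.04), and miR-19a-3p of the miR-17-92 cluster, 2.12-fold lower (log2 −1.08 ± 0.06).

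The highest ratios in this comparison, under the main processing, belonged to miR-574-5p at 7.01-fold (log2 2.81 ± 0.13), miR-466i-5p at 6.77-fold (2.76 ± 0.06) and miR-5119 at 6.54-fold (2.71 ± 0.10); miR-6978-5p stood at 3.08-fold. With normexp these 3 fell to log2 ratios of 1.24, 1.59 and 1.28, and miR-200a-3p and miR-200b-3p to 1.25 and 1.23, beside 1.35 for let-7c-5p. The offset added with normexp, and background left uncorrected, shrink log2 differences by construction, most for dim miRNAs. On the mirVana PARIS array miR-574-5p, miR-5119 and miR-200a-3p had scaled log2 levels of −4.52, −4.24 and −4.17. The lowest detected signal before scaling was 8.81 on that array and 21.6 on the exoRNeasy array. miRNAs this dim on the mirVana PARIS array could thus be compared only if higher on the exoRNeasy array, which also bears on the split of 20 and 2. All 7 let-7 members lay above the median ratio of 0.33 over the 80 miRNAs. Their median stood 1.16 above it, at percentile 99.1 of 10000 random lists of equal size and similar level. Over 14 settings that percentile ranged from 96.7, inside the central 95%, with the total gene signal, to 99.9. Those of the 14 that only scale each array by a single factor cannot move such a percentile except through the random draws. Red blood cell miRNAs went the other way, with 11 of 12 under the median of all miRNAs and a list median at −0.64 from it, at percentile 0.38. Among them miR-16-5p had a log2 ratio of −0.58 ± 0.02, miR-451a of −0.56 ± 0.02 and miR-486a-5p of −0.34 ± 0.03, while miR-92a-3p stood at 0.50. The 3 muscle miRNAs lay below the median of all too, with a log2 ratio of −0.49 ± 0.03 for miR-133a-3p and a list percentile of 4.13, inside the central 95% of random lists. Platelet and white blood cell miRNAs had a median at −0.02 from that of all miRNAs, at percentile 61.0. The largest ratio of that list was that of miR-26a-5p at 1.45 ± 0.08, with miR-126a-3p, abundant in endothelial cells and platelets, at 0.87 ± 0.04 and miR-223-3p at 0.57 ± 0.03. The liver list lay at percentile 68.9 and miR-122-5p, the main hepatocyte miRNA, at 0.19 ± 0.04. The 3 miRNAs not well above background on the mirVana PARIS array had only a bound, at least 5.88-fold higher on the exoRNeasy array for miR-429-3p, 5.85-fold for miR-483-3p and 4.98-fold for miR-1894-5p. Without scaling these bounds were smaller, at log2 1.59, 1.58 and 1.35 in the same order. The 54 miRNAs detected on the mirVana PARIS array and not on the exoRNeasy array gave no bound above 1-fold after scaling; without scaling 20 of them did. Across miRNAs, which are not independent replicates, the levels had Pearson's r of 0.893 and Spearman's rho of 0.837. The split of 20 higher and 2 lower rested on the scaling and became 5 and 22 without scaling, 4 and 45 with the 75th percentile over all probes and 7 and 14 with the labelling spike-in. It became 10 and 0 with normexp and 14 and 0 without correction; miR-144-3p then stood at −0.86 and −0.92 and miR-19a-3p at −0.15 and −0.17. The 5 without scaling were miR-574-5p, miR-466i-5p, miR-5119, miR-200a-3p and miR-200b-3p, with unscaled log2 differences of 1.84, 1.79, 1.74, 1.61 and 1.27.

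The exoRNeasy and miRNeasy advanced arrays, both from column kits of the same maker, had the fewest miRNAs past 2-fold under the main scaling, though not without scaling. Of 67 miRNAs detected on both, 64 were within 2-fold. On the exoRNeasy array miR-466i-5p, in the Sfmbt2 list by its name alone, was 2.70-fold higher (log2 1.43 ± 0.08) and miR-3095-3p 2.06-fold higher (1.04 ± 0.09). The miRNA of blood-forming cells miR-142a-3p was 2.21-fold lower there (−1.14 ± 0.06). Relative to other miRNAs the liver list stood higher on the exoRNeasy array, with 3 of 4 members above the median of all. Its log2 ratios were 0.97 ± 0.04 for miR-122-5p, 0.79 ± 0.05 for miR-192-5p, 0.45 ± 0.07 for miR-215-5p and 0.10 ± 0.02 for miR-22-3p. The median of these 4 was 0.50 above the median of all miRNAs, at percentile 98.5 of random lists. That percentile ranged from 85.4 to 98.9 over the same 14 settings, inside the central 95% with the mean of all probes and with the total gene signal.

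None of the other tissue lists left the central 95% in this comparison. Red blood cell miRNAs had a median 0.08 above that of all miRNAs, at percentile 76.5. Over the same 14 settings it ranged from 2.53, with normexp and a median of −0.029, to 77.3. Their members went apart, with miR-144-3p at −0.86 ± 0.05 and miR-451a at −0.50 ± 0.02 against miR-92a-3p at 0.39 ± 0.04 and miR-25-3p at 0.34 ± 0.04. The muscle miRNAs miR-133a-3p and miR-133b-3p lay at 0.84 ± 0.06 and 0.80 ± 0.04 and miR-1a-3p at −0.0014 ± 0.04, with a list percentile of 94.0. The let-7 list was at percentile 84.1, with let-7d-5p at 0.86 ± 0.09 and let-7a-5p at 0.62 ± 0.04, and the platelet and white blood cell list at percentile 11.6. The 4 low-GC miRNAs fixed in advance as reported losses of phenol extraction at low input, among them miR-21a-5p at −0.24 ± 0.03 and miR-29b-3p at −0.19 ± 0.07, all lay under the median of all miRNAs, at percentile 7.27. The 13 miRNAs numbered 1000 or higher, which entered the miRNA registry late, had a median at −0.31 from that of all, at percentile 0.96. Below the median of all lay 10 of them, with miR-5126 1.99-fold lower and miR-3473f 1.83-fold lower, and above it 3, with miR-3095-3p at a log2 ratio of 1.04. The 54 with lower numbers or named let-7, the rest of the 67, stood at percentile 98.9, which restates the same split. Of 16 miRNAs detected on the exoRNeasy array and not on the miRNeasy advanced array, 4 were at least 2-fold higher by their bound. These were miR-200b-3p, at least 2.65-fold, miR-5119 and miR-6978-5p, each at least 2.10-fold, and miR-200a-3p, at least 2.02-fold. Without scaling 12 of the 16 were at least 2-fold higher. The 4 miRNAs detected in the opposite way had bounds of at most 1.102-fold, and none over 1-fold without scaling. Across miRNAs r was 0.952 and rho 0.904. The split of 2 higher and 1 lower became 29 and 0 without scaling, 12 and 0 with the 75th percentile over all probes, 39 and 0 with the labelling spike-in, and 1 and 4 with either median or quantile scaling. It became 0 and 0 with normexp, where miR-466i-5p stood at 0.50 ± 0.03, miR-3095-3p at 0.056 ± 0.02 and miR-142a-3p at −0.63 ± 0.03, and 0 and 0 without background correction.

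Between the miRNeasy advanced and mirVana PARIS arrays, a direct comparison of the kits used as their makers describe, red blood cell miRNAs stood lower on the miRNeasy advanced array relative to other miRNAs. Muscle miRNAs did so too, though not past the bound for lists without background correction. The whole let-7 list stayed inside the central 95%, though not with every member left out. miR-133b-3p and miR-133a-3p, which act in heart and skeletal muscle, were 2.54-fold and 2.52-fold lower (log2 −1.34 ± 0.04 and −1.33 ± 0.05), and no other of the 71 miRNAs detected on both arrays was 2-fold lower. Neither stayed 2-fold lower with normexp, at −0.59 ± 0.02 and −0.31 ± 0.02, or without background correction, at −0.67 ± 0.02 and −0.38 ± 0.02. Both settings shrink log2 ratios by construction, so the loss of these calls does not decide whether the difference is real. At least 2-fold higher were 10 miRNAs, which included let-7c-5p at 3.00-fold (1.58 ± 0.06), let-7b-5p at 2.57-fold (1.36 ± 0.05) and let-7a-5p at 2.10-fold (1.07 ± 0.05), and the highest were miR-1249-3p at 4.05-fold (2.02 ± 0.13) and miR-3473f at 3.74-fold (1.90 ± 0.09). These 12 differences exceeded 3 times the spot error, but the directions of 8 of the 10 higher miRNAs, the let-7 members included, turned without scaling, where the whole array shifted by −1.80.

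Relative to the median of all 71 miRNAs, which no scaling by a single factor alters, the red blood cell list had a median at −0.56, with 12 of 12 members below it, at percentile 0.37. With normexp that percentile was 1.45, and it lay inside the central 95%, at up to 12.3, when any 1 of 6 members was left out. The log2 ratios of the members reached −0.76 ± 0.06 for miR-93-5p, −0.74 ± 0.04 for miR-144-3p and −0.73 ± 0.02 for miR-16-5p, and miR-451a had −0.06 ± 0.03. The 3 muscle miRNAs had a median at −1.51, at percentile 0.39, which became −0.76 with normexp, at percentile 2.20, and −0.77 without background correction, at percentile 2.88 and so inside the central 95%. Their main values included a log2 ratio of −0.40 ± 0.04 for miR-1a-3p; miR-133a-3p and miR-133b-3p are close in sequence, so their probes are not independent measures. All 7 let-7 members lay above the median of all, by a median of 0.54, at percentile 95.02 and so inside the central 95%. With each member left out in turn that percentile ranged from 88.5 to 99.6, inside for 5 of 7. With normexp it ranged from 96.4 to 99.9, inside for 1 of 7. The 4 liver miRNAs lay below it, at percentile 37.7, with miR-122-5p at −0.78 ± 0.04. Platelet and white blood cell miRNAs were at percentile 75.3, with miR-126a-3p at 0.89 ± 0.04, miR-142a-3p at 0.74 ± 0.04 and miR-21a-5p at 0.62 ± 0.04. Of the 63 miRNAs detected on the mirVana PARIS array and not on the miRNeasy advanced array, 1 had a bound over 1-fold after scaling, miR-30d-5p at 1.32-fold, and 55 without scaling. Across miRNAs r was 0.923 and rho 0.893. The split of 10 higher and 2 lower became 0 and 57 without scaling, 0 and 56 with the 75th percentile over all probes and 0 and 53 with the labelling spike-in, and 7 and 0 both with normexp and without background correction.

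**Figure D2:**
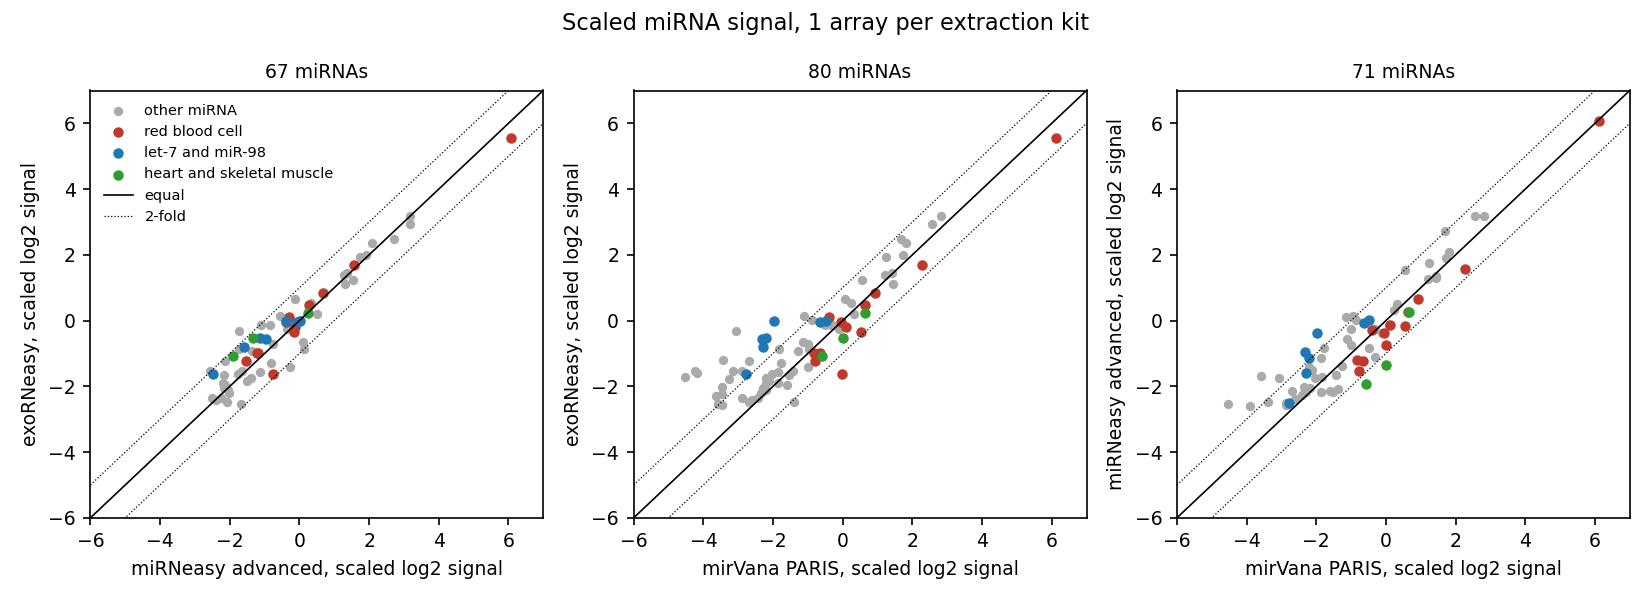
Scaled log2 signal of miRNAs detected on both arrays of each pair of kits, with 1 point per miRNA, red blood cell miRNAs in red, let-7 in blue and heart and skeletal muscle miRNAs in green. The solid line marks equal scaled signal and the dotted lines a 2-fold difference; 64 of 67 miRNAs lie inside the dotted lines for exoRNeasy against miRNeasy advanced, 58 of 80 for exoRNeasy against mirVana PARIS and 59 of 71 for miRNeasy advanced against mirVana PARIS.

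The percentiles of the remaining lists lay inside the central 95% of level-matched random lists. The miR-29 and miR-30 list lay at percentiles 44.5, 13.0 and 18.3 for exoRNeasy against miRNeasy advanced, exoRNeasy against mirVana PARIS and miRNeasy advanced against mirVana PARIS. In the same order the 3 G-rich or C-rich miRNAs miR-1224-5p, miR-1895 and miR-5126 lay at 4.57, 71.5 and 90.9, the 5p arms at 82.8, 71.2 and 71.4 and the 3p arms at 37.3, 10.2 and 26.0. The low-GC list lay at 10.9 and 59.6 in the comparisons with mirVana PARIS, the miRNAs numbered 1000 or higher at 80.1 and 97.47 and those with lower numbers at 19.7 and 6.67. Of 36 list percentiles computed, for 12 of the 16 lists in 3 comparisons, 7 fell outside the central 95%, where 1.8 would be expected by chance. Lists and comparisons are not independent, so the number outside can stray further from 1.8. Lists share members or complement each other, as the high-numbered and low-numbered miRNAs do, which give 2 of the 7 from the same split. Each pair of comparisons also shares an array.

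**Figure D3:**
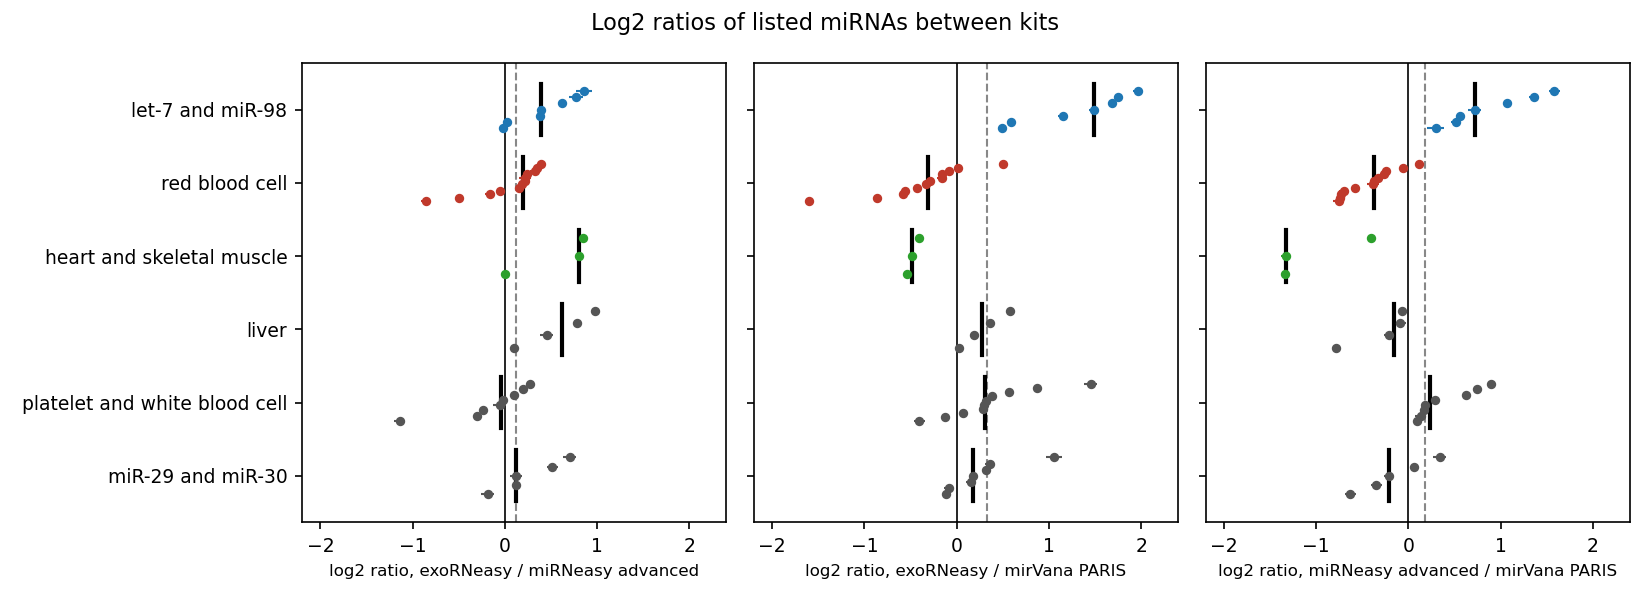
Log2 ratios of single miRNAs in 6 lists for the 3 pairs of kits, with the standard error between replicate spots as horizontal lines, the list median as a thick bar and the median of all miRNAs as a dashed line. Relative to that dashed line the let-7 median lies 1.16 to the right for exoRNeasy against mirVana PARIS and 0.54 for miRNeasy advanced against mirVana PARIS, and the red blood cell median lies at −0.64 and −0.56 from it.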

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

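Of the control probes outside the comparisons, 4 kinds that are neither spike-ins nor negative controls were well above background on all 3 arrays, and the files do not state their targets. The brightest probe of hur_1 had an unscaled log2 signal of 9.08 on the exoRNeasy array, 7.01 on the miRNeasy advanced array and 9.40 on the mirVana PARIS array. In the same order the brightest probe of hur_2 had 10.53, 9.21 and 10.43, that of hur_4 had 6.72, 5.10 and 6.70, and that of mr_1 had 6.90, 5.58 and 6.38. Each was lowest on the miRNeasy advanced array, and over 13 such probes the median difference from that array was 1.55 for exoRNeasy and 1.51 for mirVana PARIS, beside 0.96 and 1.64 for the miRNAs. Whether the differences between kits were biological was not tested for these probes.

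The test against the spike-ins in this part and the resampled range were chosen after the signals were seen, and the test by brightness was written before. The mirVana PARIS array was brighter than the miRNeasy advanced array by a median of 1.64 log2 units after labelling of the same RNA mass. A difference in labelling or hybridisation would move the spike-in probes alike, but the larger mean difference of the spike-in kinds was 0.13. More background left on the mirVana PARIS array would raise its dim probes most. The difference would then be larger among dim miRNAs than among bright ones. The brighter 34 miRNAs differed by 1.72 and the dimmer 33 by 1.57, a ratio of 1.099 (0.88 to 1.36 in 95% of resamples). These miRNAs were detected on every array, which left out 63 detected on the mirVana PARIS array and not on the miRNeasy advanced array. Of those, 18 were at least 2-fold brighter on the mirVana PARIS array by their unscaled bound. Dim miRNAs with a large difference can thus be missing from the dimmer 33. The test therefore cannot decide on background for dim miRNAs, where it stays open. As the source of the difference in the brighter 34, background is argued against. Mean negative-control signals were 4.92 on the miRNeasy advanced array and 5.49 on the mirVana PARIS array. The 75th percentiles over the probes detected on all 3 arrays were 74.1 and 259 in the same order. A larger share of miRNA in the labelled RNA of that extract remains a candidate explanation, and with 1 extract per kit it cannot be separated from differences between the serum portions or in how the RNA mass was measured.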

How the results depend on the processing

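Chosen after the data were seen were the labelling spike-in scaling, both settings on median spot signals and all list percentiles by setting. No paired analysis was possible because each kit had 1 array, and slide and scan were shared, so neither was a block. The alternatives on mean spot signals were not run, since the files used here hold medians. Signal over background limits the detected sets, as most probes were not well above background. Scaling moved the median of all log2 ratios, by up to −1.80 for miRNeasy advanced against mirVana PARIS, −1.43 for exoRNeasy against mirVana PARIS and 0.95 for exoRNeasy against miRNeasy advanced. A single factor per array shifts all ratios alike, so it left every miRNA on its side of the median of all. Of the counts and median differences under these alternatives, 71 values stayed within 1.5 times, or for medians within 0.1 log2 units, and 66 moved further. The value table and keeping outlier spots moved none of the counts by over 1.5 times. Where no construction is named, the cause was not tested.

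For exoRNeasy against miRNeasy advanced, the 2 higher and 1 lower miRNAs became 12 and 0 with the 75th percentile over all probes, 29 and 0 without scaling, 39 and 0 with the labelling spike-in, 1 and 4 with median scaling and 1 and 4 with quantile normalisation. They were 0 and 0 with normexp and 0 and 0 without background correction. Both settings changed the signal to pixel medians as well as the background step, and normexp added an offset, and these were not separated. An offset, or background left in, shrinks log2 ratios by construction. Fewer miRNAs past 2-fold under these settings, here and below, is therefore no failed check of the calls. The higher miRNAs numbered 5 with the total gene signal, 7 with the mean of all probes and 6 without a filter, and the detection flag gave 6 higher and 4 lower. At 1.5-fold there were 13 and 5, and at 4-fold 0 and 0.

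For exoRNeasy against mirVana PARIS, the 20 higher and 2 lower became 4 and 45 with the 75th percentile over all probes, 5 and 22 without scaling, and 7 and 14 with the labelling spike-in. The higher miRNAs numbered 12 with quantile normalisation, 12 without a filter, 11 in the brighter part and 10 among miRNAs detected on all 3 arrays. The last 2 settings left the ratios unchanged and compared 69 and 67 miRNAs in place of 80. The calls lost there belonged to the miRNAs left out. In the last setting these were the 13 miRNAs detected on the mirVana PARIS and exoRNeasy arrays only. Normexp gave 10 and 0, no background correction gave 0 lower, the mean of all probes 5 lower, and 4-fold 5 and 0. With the 75th percentile over all probes the direction turned for miR-3095-3p, at −0.087, and miR-3473f, at −0.40.

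For miRNeasy advanced against mirVana PARIS, the 10 higher and 2 lower became 0 and 56 with the 75th percentile over all probes, 0 and 57 without scaling and 0 and 53 with the labelling spike-in. Without a filter 6 were higher, the mean of all probes gave 5 lower, and normexp and no background correction each gave 0 lower. At 1.5-fold there were 20 and 9, and at 4-fold 1 and 0. The direction of 8 higher miRNAs turned under those first 3 scalings, in that order with log2 ratios of −0.73, −0.76 and −0.63 for miR-3473b, −0.70, −0.73 and −0.60 for let-7a-5p, −0.67, −0.70 and −0.57 for miR-5126, −0.53, −0.56 and −0.42 for miR-5128, −0.47, −0.50 and −0.36 for miR-296-5p, −0.45, −0.48 and −0.35 for miR-466i-5p, −0.41, −0.44 and −0.31 for let-7b-5p, and −0.19, −0.22 and −0.089 for let-7c-5p. The shift of the whole array accounts for these.

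With all probes of a miRNA required above background, the arrays had 44 miRNAs for exoRNeasy, 41 for miRNeasy advanced, 75 for mirVana PARIS and 38 on all 3. The detection flag gave 134, 97, 161 and 88. The unscaled median difference was 0.55 with normexp and 0.64 without background correction for exoRNeasy minus miRNeasy advanced. For exoRNeasy minus mirVana PARIS it was −0.39 and −0.38, and −0.81 with the total gene signal. For miRNeasy advanced minus mirVana PARIS it was −0.93 and −1.05, and −1.76 with the total gene signal. List percentiles were computed over 14 settings, with 2000 random lists each. Several of these only scale each array by a single factor, which leaves a list's place relative to all miRNAs unchanged, and the value table holds the same intensities. Such settings are no check of the percentiles. The red blood cell percentile lay between 0 and 0.88 for exoRNeasy against mirVana PARIS and between 0.075 and 1.45 for miRNeasy advanced against mirVana PARIS. The let-7 percentile lay between 96.7 and 99.9 and between 80.2 and 97.4 for the same pairs, and the muscle percentile between 0.23 and 2.88 for the second. The let-7 percentile of the first pair left its side of the bound with the total gene signal alone, and the muscle percentile without background correction alone. With each member left out in turn under normexp, the red blood cell percentile of the second pair reached 12.3.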

Other observations

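The 20 miRNAs higher on the exoRNeasy array than on the mirVana PARIS array also held members of lists that as a whole stayed inside the central 95%. miR-125b-5p, a relative of the nematode timing miRNA lin-4, was 2.38-fold higher, miR-26a-5p 2.73-fold, miR-30c-5p 2.08-fold, miR-328-3p 2.77-fold and miR-652-3p 2.52-fold. The passenger strand let-7d-3p was 2.34-fold higher beside 2.22-fold for let-7d-5p. None of these 7 stayed 2-fold higher with normexp or without scaling. The miRNAs in this paragraph outside the naming rule were named after their values were seen. The lymphocyte miRNA miR-150-5p, at a scaled log2 level of −3.27 ± 0.02, and the pancreatic islet miRNA miR-375-3p, at −3.36 ± 0.04, were well above background on the mirVana PARIS array alone. Their measured scaled levels on the exoRNeasy array, not well above background there, were −3.04 and −2.64. They thus cannot be called particular to the mirVana PARIS extract.

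Of the tests that follow, those of red blood cell RNA, of the let-7 percentile under normexp, of families without let-7 and with each miRNA left out in turn were chosen after the results were seen, and the others were written before.

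The let-7 family stood higher on the exoRNeasy array than on the mirVana PARIS array relative to other miRNAs. A trend with probe brightness is argued against, because the let-7 median lay at percentile 99.06 of level-matched random lists and at 98.8 or above with any member left out, though at 96.7 with the total gene signal. Under normexp the let-7 shift fell to 0.52 of its value, from 1.16 to 0.60, which met neither bound set beforehand. Normexp also used pixel medians and added an offset of 50, which by itself shrinks differences on the log2 scale. These were not separated, so the background correction may account for part of its size. It is argued against as the whole of it, since the spread of all ratios fell to 0.59 of its value too and let-7 still lay at percentile 99.0 under normexp, and at 97.95 or above with any member left out. A difference in let-7 recovery between kits and one between serum portions both remain open, and probes of similar sequence cannot be counted as independent.

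Red blood cell miRNAs stood lower on the exoRNeasy than on the mirVana PARIS array, with 91.7% of the 12 detected members under the median of all miRNAs. More red blood cell RNA in the serum behind the mirVana PARIS array was not settled, since that share is the pattern itself. In miRNeasy advanced against mirVana PARIS the list lay low too, at −0.56, but miR-451a only at −0.24 under the main processing. Its unscaled difference there ranked 26 from the lowest of 71 miRNAs. That rank was 2 with normexp and 4 without background correction. In exoRNeasy against mirVana PARIS miR-451a lay at −0.89 from the median of all, below the list median of −0.64. Both comparisons share the mirVana PARIS array, so these values do not decide. Of the 12 members, 2 also belong to another list that was not built on names, and many are made in other cells as well. Lower recovery of these miRNAs by the other kits was not tested and stays open.

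A hypothesis was that related miRNAs shift together between kits. Pairs with the same number in the name differed less in log2 ratio than random level-matched pairs. The percentiles were 0.11, 0.02 and 0.19 for exoRNeasy against miRNeasy advanced, exoRNeasy against mirVana PARIS and miRNeasy advanced against mirVana PARIS, over 30, 39 and 30 pairs. These pairs came from only 22, 29 and 22 miRNAs, many of them in several pairs, while the miRNAs of random pairs were drawn independently. The random spread can thus be too narrow, and these percentiles and the next too extreme. Without let-7 the percentiles were 1.63, 0.06 and 0.24 over 9, 18 and 9 pairs, and the first rose to 5.45, above the bound of 5, with a miRNA left out. This is consistent with recovery that depends on sequence, but cross-hybridisation between similar probes would give the same pattern and was not tested. Pairs with different numbers in the name whose genes lie within 10 kb of each other, such as miR-144-3p and miR-451a, gave percentiles of 10.6, 44.7 and 1.38. A different number does not ensure unlike sequence. The second percentile, 35.2 to 69.0 with each miRNA left out, lay above the bound of 5 that a shift shared in all 3 comparisons had to meet. With only 6 pairs of 9 miRNAs a shared shift can be missed, so no conclusion is drawn. The mean differences of 0.40, 0.69 and 0.31 lay under the random medians of 0.61, 0.72 and 0.69. A shift shared by such neighbours stays open.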
